A study of Mus musculus with 36 samples.

How the data were processed

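Lung RNA of 36 mouse samples was hybridised to single-colour Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample, and the deposited values of 45101 probe sets were analysed. Per the labels' protocols, mice received 3 intraperitoneal injections of 50 µg ovalbumin (OVA) in 0.1 ml phosphate-buffered saline (PBS) on days 1, 4 and 7, and from day 12 an intranasal challenge of 20 µg OVA in 30 µl PBS every week for 9 weeks. Control mice received PBS on the same schedule. The labels give 5 kinds of mice, all described as female. WT mice are C57BL/6 wild type. KitWsh mice carry the sash mutation at Kit and lack mast cells. KitWsh_MC, KitWsh_MCifngR and KitWsh_MCigeR mice are KitWsh mice whose engraftment label is MC, MCifngR or MCigeR. The genotype label of the last also names FcεRIγ deficiency, and the protocol lists IFN-γR1-deficient and FcεRIγ-deficient mice among the strains used. The engraftment codes are not spelled out in the sources used here. They are read as mast cells from wild-type, IFN-γ receptor-deficient and IgE receptor-deficient donors, which the array cannot check. The FcεRIγ deficiency in the genotype label could also be that of the recipient mice, and comparisons with KitWsh_MCigeR mice would then differ in the recipient too. Each OVA group and the WT PBS group had 4 arrays, and each other PBS group had 3.

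The deposited values are log2 intensities that the authors made with GCRMA, per the submitters' processing notes, whose version is not given in the sources used here. GCRMA corrects each probe for background by its sequence, normalises the arrays by quantiles and summarises the probes of a probe set. The values ran from 2.19 to 15.9. Low values are set by the background model, and genes near that floor have no order. No further normalisation was applied.

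The 64 control probe sets were left out of the tests. GEO's platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, the last being unnamed here. Among probe sets with 1 symbol, the probe set with the highest mean over the 36 arrays stood for its gene, giving 18194 genes. The 11600 genes with a log2 value over 5 in at least 3 arrays were tested. Some annotated symbols are old.

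Limma 3.58.1 in R 4.3.3 fitted 10 group means to the 36 arrays (lmFit and eBayes, 26 residual degrees of freedom). The 14 comparisons were OVA against PBS in each of the 5 kinds of mice, the difference of that response between kinds in 4 pairs, OVA-treated mice of different kinds in 3 pairs, and PBS-treated mice in 2 pairs. A gene was called at an adjusted p (Benjamini-Hochberg, two-sided) under 0.05. Counts at an unadjusted p under 0.05 are given beside some calls. If no gene differed, a share of about 0.05 of the tested genes would still reach it, so such a count alone shows no difference. Each log2 fold change is given ± its standard error, and each group mean ± the standard deviation (SD) between arrays. A fold is written as "at least" where every array of the lower group lay under log2 5, and is then the higher group's mean against 5. No such fold is given where the higher mean lay under 5 as well, as for Tpsb2 in KitWsh_MC mice. Such a log2 difference rests on low values in both groups. No pairing was used. The labels do not say that the samples of a group are separate animals, so p-values measure the spread between these samples, and the number of arrays limits the precision.

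Before the data were examined, 37 gene lists for cell types and processes, the comparisons, the filter, most of the other settings tried and the rule for the genes to be named were fixed. The named genes were the 10 highest and 10 lowest called fold changes between OVA and PBS WT mice, 5 and 5 in each other comparison (all of them where 10 or fewer were called), 2 to 4 members of a described list with the smallest adjusted p, and always Kit, Ifngr1, Fcer1g and the mast cell list. Immunoglobulin segments and predicted or clone-named genes were passed over. Other genes given by name, such as single circadian clock transcripts, were chosen after their values were seen.

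The shift of each list against all other genes was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists of a comparison, and again with an estimated correlation. The numbers of list members called over all genes and adjusted over the list alone were counted. Similarity between responses was Pearson's r across genes, which are not independent replicates, and has no p-value. The pairs of responses share no arrays.

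The procedure was tested on simulated data for 11600 genes of which 200 were changed. With the spread of all arrays it recovered 50% of genes changed 2-fold and 90% of those changed 4-fold between OVA and PBS WT mice. For the difference of the response between KitWsh_MCifngR and KitWsh_MC mice it recovered 13% and 58%. With the spread taken without KitWsh_MCigeR PBS array 2 these were 71% and 97%, and 45% and 88%. False calls made up 3.33% to 9.52% of the calls over the comparisons simulated. These shares hold for the simulated data only. They do not show the effect of arrays that differ in quality or of genes that move together. Among the real arrays of KitWsh_MC mice, a split that mixed OVA and PBS arrays called 798 genes, against 762 for the real split. Recovery and false calls in the real data may therefore differ from those simulated.

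Other settings chosen at that stage were an estimated correlation in camera, a filter at log2 7 in 3 arrays, no filter, centring each array on its median, quantile normalisation of the genes, the mean of a gene's probe sets, each array left out in turn, only the compared groups in the fit, eBayes with trend and robust options, array weights, and, for similarity, only genes called in either comparison. Chosen after the data were seen were leaving out the array of lowest correlation with the others, leaving out 4 arrays doubted for their quality or their Kit, Xist or Y-linked values, and leaving out the first while adding the difference between the 3' and 5' beta-actin control probe sets as a covariate.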

Results

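The arrays compared lungs of OVA-challenged and PBS-treated mice with mast cells (WT), without them (KitWsh), and after engraftments labelled MC, MCifngR and MCigeR, in a mouse model of severe asthma. The codes are read as mast cells that differ in their receptors, but the genotype label of KitWsh_MCigeR mice, which names FcεRIγ deficiency, could also describe the recipient. A total of 36 arrays fell into 10 groups of 3 or 4. The highest correlation between any 2 arrays was 0.994, and no 2 were identical.

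KitWsh_MCigeR PBS array 2 stood apart from all others. Its median Pearson r with the other arrays, across the 11600 tested genes, was 0.543, where the other 35 had 0.882 to 0.971. The difference between its 3' and 5' beta-actin control values, which grows as RNA breaks down, was 8.43 log2 units. It averaged 1.29 ± 0.12 in WT OVA (SD, n = 4), 1.37 ± 0.27 in WT PBS (n = 4), 1.74 ± 0.61 in KitWsh OVA (n = 4), 2.07 ± 0.38 in KitWsh PBS (n = 3), 3.34 ± 1.93 in KitWsh_MC OVA (n = 4), 2.92 ± 0.55 in KitWsh_MC PBS (n = 3), 3.38 ± 1.08 in KitWsh_MCifngR OVA (n = 4), 3.90 ± 0.29 in KitWsh_MCifngR PBS (n = 3) and 1.95 ± 0.49 in KitWsh_MCigeR OVA (n = 4). The KitWsh_MC and KitWsh_MCifngR groups thus had the larger differences, and KitWsh_MC OVA array 2 had the second-lowest correlation, 0.882, with a beta-actin difference of 6.23. Because all 10 groups shared 1 estimate of the spread, the low-correlation array also lowered the number of genes called elsewhere, and each count is given with and without it. Outside OVA against PBS in KitWsh_MCigeR mice, the genes of largest change kept at least 63.9% of their log2 size whichever 1 array was left out (least in Eif2s3y). A lost call thus need not mean a lost size. These genes were picked for their size in the same arrays, so a kept size does not show that a difference holds. For the same reason, single arrays of the genes of largest change were likely from the start to lie on the called side. Eif2s3y was high in only 2 of 4 KitWsh_MCifngR OVA arrays.

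**Figure D1:**
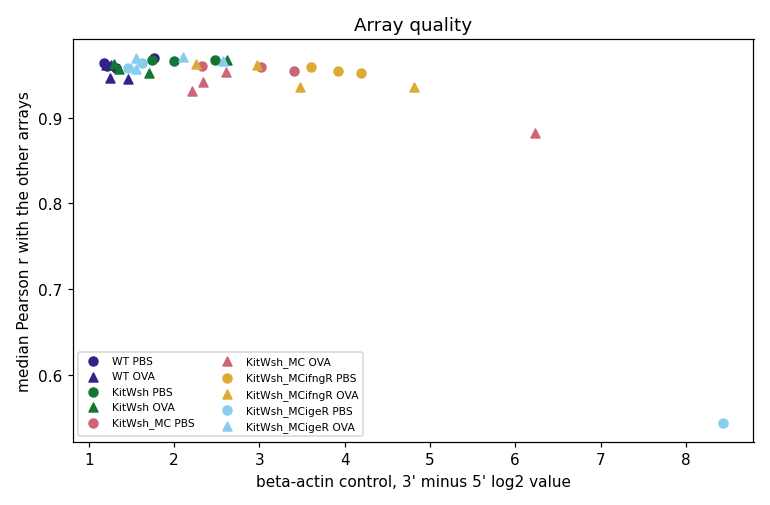
Each point is an array. The horizontal axis gives the 3' minus 5' log2 value of the beta-actin control and the vertical axis the median Pearson r with the other 35 arrays. KitWsh_MCigeR PBS array 2 lies at 8.43 and 0.543, away from the rest.

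Kit separated WT from KitWsh lungs. It averaged 10.06 ± 0.18 in WT PBS (SD, n = 4) and 5.50 ± 0.24 in KitWsh PBS (n = 3), a difference of −4.56 ± 0.58 (adjusted p = 5.99e-05), and between 5.10 and 6.30 in every other KitWsh group. WT OVA array 4 had a Kit value of 6.90, against 10.61 to 10.97 in the other 3 WT OVA arrays, with an Xist value of 10.69 and a mean of 7.28 over 3 Y-linked transcripts (Eif2s3y, Kdm5d and Uty). KitWsh_MCifngR OVA arrays 2 and 3 had Y-linked means of 7.71 and 7.30 and Xist values of 7.30 and 7.70. In no other array did the Y-linked mean pass 2.66, and all mice are described as female. These 3 arrays are called by their labels throughout. Ifngr1 lay between 8.40 and 9.85 and Fcer1g between 8.11 and 10.29 in group means. Neither differed between any kinds of mice compared here in OVA or PBS mice (adjusted p from 0.235 to 0.983). Whole lung holds other cells with both transcripts, so these values do not check the engrafted cells' genotypes.

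The mast cell transcripts Cma1, Cpa3 and Tpsb2 were scarce in WT and KitWsh lungs and rose with challenge in KitWsh_MC lungs. Cma1, a mast cell chymase, averaged 2.53 ± 0.26 in WT OVA (SD, n = 4), 3.54 ± 0.83 in KitWsh OVA (n = 4), 7.48 ± 0.49 in KitWsh_MC OVA (n = 4), 7.79 ± 1.54 in KitWsh_MCifngR OVA (n = 4) and 5.02 ± 0.55 in KitWsh_MCigeR OVA (n = 4). Cpa3, the mast cell carboxypeptidase, averaged 3.13 ± 0.07, 3.17 ± 0.16, 6.30 ± 0.83, 7.40 ± 1.70 and 4.49 ± 0.74 in the same groups, and the tryptase gene Tpsb2 2.37, 2.41 ± 0.06, 4.88 ± 0.95, 4.83 ± 1.40 and 3.24 ± 0.17. Hdc, Gata2 and Rab27b were above 7 in WT lungs too. Of the 18 listed mast cell genes, 7 passed the filter, namely these 6 and Fcer1a.

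**Figure D2:**
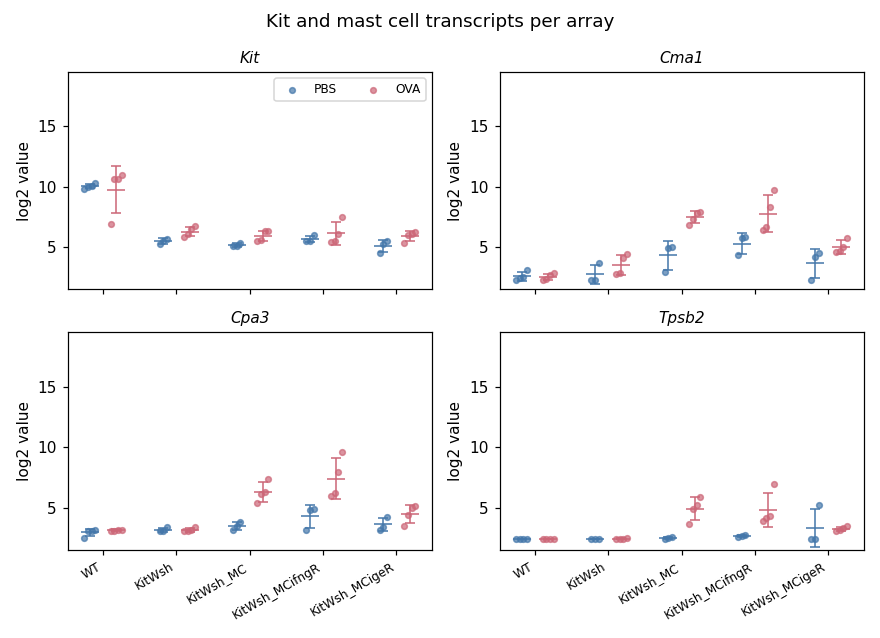
Log2 values of Kit, Cma1, Cpa3 and Tpsb2 in each array (points) by kind of mouse, PBS in blue and OVA in red, with group means and SD (bars). Kit is near 10 in WT arrays other than WT OVA array 4 (6.90), and Cma1 averages 7.48 in KitWsh_MC OVA and 3.54 in KitWsh OVA.

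What repeated OVA challenge did to lungs with mast cells was asked first. In WT mice Clca1 and Chil4 rose most. Clca1, a goblet cell product, rose by 8.09 ± 1.63 (adjusted p = 0.0118), from 5.24 ± 2.39 to 13.33 ± 1.79 (SD, n = 4 each), and Agr2 by 4.29 ± 0.80, at least 6.02-fold. The chitinase-like gene Chil4 rose by 7.60 ± 1.18 (adjusted p = 0.00171), at least 44.6-fold, and Arg1, a product of macrophages activated by type 2 cytokines (IL-4 and IL-13), by 4.63 ± 0.80, at least 6.06-fold. Fer1l6 (4.50 ± 0.92, at least 3.94-fold), Slc26a4 (4.34 ± 0.97), Saa3 (4.28 ± 0.91), Scin (3.48 ± 0.84, at least 2.07-fold), Fxyd4 (3.33 ± 0.59, at least 2.33-fold) and Timp1 (3.24 ± 0.68) rose too. Spon2 (−2.91 ± 0.63, at least 3.76-fold), Acaa1b (−2.90 ± 0.57), Adipoq (−2.86 ± 0.67), Inpp4b (−2.78 ± 0.52, at least 1.17-fold), Fabp1 (−2.75 ± 0.58), Arntl (−2.59 ± 0.54), Npas2 (−2.39 ± 0.33, at least 1.04-fold), Myo1h (−2.33 ± 0.60, at least 3.23-fold), Dnajb14 (−2.26 ± 0.54) and Zfp626 (−2.09 ± 0.48, at least 1.04-fold) fell. For all 20 genes each of the 4 OVA arrays lay on the called side of the PBS mean.

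In total 158 genes were called between OVA and PBS WT mice, 62 higher and 96 lower, of 11600 tested. With KitWsh_MCigeR PBS array 2 left out there were 1081, 461 higher and 620 lower. The higher genes were 39.2% of the calls, 50.5% after quantile normalisation and 52.3% after centring. Leaving out any 1 of the compared arrays other than WT PBS array 4 moved the count by over 1.5 times, to between 14 (WT OVA array 1) and 593 (WT OVA array 4, the array of low Kit). Chil4, Arg1, Fxyd4, Inpp4b and Npas2 kept their call whichever array was left out, and the other 15 named genes lost it without at least 1 array.

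Among the lists in WT mice, 4 of 10 goblet cell genes rose and none fell, with 9 higher when adjusted over the list alone (Clca1, Agr2, Slc26a4 and Fcgbp, 3.16 ± 0.77). The list shifted up (adjusted p = 2.93e-12, and adjusted p = 0.181 with an estimated correlation). Of 14 IL-4 and IL-13 response genes 3 rose and none fell, 5 rising when adjusted over the list alone (Chil4, Arg1 and Retnla, 2.03 ± 0.52; adjusted p = 1.33e-05, and adjusted p = 0.347 with an estimated correlation). Of 13 inflammatory chemokine and acute response genes only Saa3 rose, 7 when adjusted over the list alone (adjusted p = 5.14e-06, and adjusted p = 0.347 with an estimated correlation). Fkbp11 (1.77 ± 0.38) was the only riser of 12 plasma cell genes, 3 rising when adjusted over the list alone (adjusted p = 4.32e-05, and adjusted p = 0.347 with an estimated correlation), and Cd5 (1.71 ± 0.43) that of 14 T cell genes, 2 rising when adjusted over the list alone (adjusted p = 0.00168, and adjusted p = 0.71 with an estimated correlation). Monocyte and macrophage genes had none of 17 called by limma, and 5 rising and 1 falling when adjusted over the list alone (adjusted p = 5.22e-05, and adjusted p = 0.558 with an estimated correlation). None of 20 IFN-γ response genes was called by limma (2 rose adjusted over the list alone; adjusted p = 0.000125, and adjusted p = 0.71 with an estimated correlation). Circadian clock genes moved both ways: Tef (1.33 ± 0.28) and Ciart (1.45 ± 0.36) rose, Npas2 and Arntl fell, and 8 of 12 were not called, 5 rising and 3 falling when adjusted over the list alone.

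**Figure D3:**
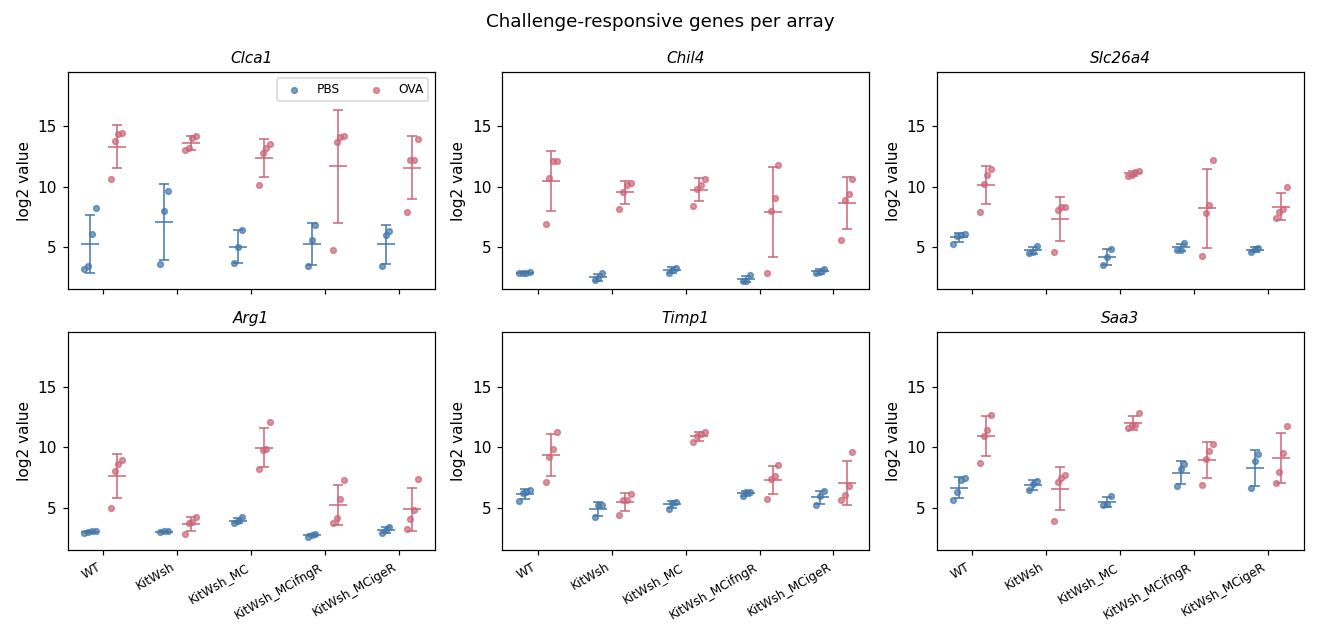
Log2 values of Clca1, Chil4, Slc26a4, Arg1, Timp1 and Saa3 in each array (points) by kind of mouse, PBS in blue and OVA in red, with group means and SD (bars). Clca1 averages 13.63 in KitWsh OVA and 13.33 in WT OVA, while Timp1 averages 5.44 and 9.36 there and 10.91 in KitWsh_MC OVA.

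The response of mice without mast cells was examined next. In KitWsh mice Chil4 rose by 7.04 ± 1.27 (adjusted p = 0.016), from 2.50 ± 0.31 (SD, n = 3) to 9.55 ± 0.95 (n = 4), at least 23.4-fold. The macrophage products Retnla (2.45 ± 0.56) and Chil3 (2.23 ± 0.41) and the myeloid receptor genes Csf2ra (2.40 ± 0.58) and Cd200r4 (2.33 ± 0.50) rose too. Clca1 averaged 13.63 ± 0.57 in OVA and 7.08 ± 3.13 in PBS KitWsh mice and was not called. Dcdc2a (−1.72 ± 0.37), Rbp7 (−1.58 ± 0.34, at least 1.54-fold), Asgr1 (−1.54 ± 0.35), Olfml2b (−1.38 ± 0.25) and Adnp2 (−1.31 ± 0.24) fell. For all 10 genes each of the 4 OVA arrays lay on the called side of the PBS mean.

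The count in KitWsh mice was 72, 16 higher and 56 lower, and 760 (162 and 598) without KitWsh_MCigeR PBS array 2. The share of higher genes was 22.2%, 42.9% after quantile normalisation and 38.5% after centring, and the median of all genes was −0.10. Lower genes stayed in the majority after quantile normalisation (8 of 14) and after centring (8 of 13). Leaving out any 1 of the 7 compared arrays moved the count by over 1.5 times, to between 0 (KitWsh OVA array 2, limma) and 133 (KitWsh OVA array 1), and none of the 10 named genes kept its call under every omission. An unadjusted p under 0.05 was reached by 1514 genes with all arrays and by 898 where limma called 0. Of the IL-4 and IL-13 response genes 3 rose, 4 when adjusted over the list alone (adjusted p = 1.60e-07, and adjusted p = 0.114 with an estimated correlation). No goblet cell gene was called by limma, while 7 of 10 rose when adjusted over the list alone (adjusted p = 5.70e-10, and adjusted p = 0.114 with an estimated correlation). The same held for T cell genes, with 5 of 14 rising adjusted over the list alone (adjusted p = 1.55e-08, and adjusted p = 0.114 with an estimated correlation), and plasma cell genes, with 6 of 12 (adjusted p = 2.98e-08, and adjusted p = 0.114 with an estimated correlation).

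In KitWsh mice engrafted with MC cells, Clca1, Slc26a4, Chil4, Saa3 and Arg1 rose most. Clca1 rose by 7.39 ± 1.76, Slc26a4 by 6.93 ± 1.05 (at least 69.1-fold), Chil4 by 6.66 ± 1.27 (at least 27.3-fold), Saa3 by 6.53 ± 0.98 and Arg1 by 6.05 ± 0.86 (at least 31.3-fold), with n = 4 OVA and n = 3 PBS arrays. The eosinophil chemokine Ccl11 rose by 4.49 ± 0.81 (at least 4.63-fold) and Ccl8 by 5.01 ± 0.86. Of the mast cell genes Cpa3 (2.83 ± 0.56, at least 2.46-fold), Cma1 (3.16 ± 0.64) and Tpsb2 (2.42 ± 0.53) rose. Fabp1 (−3.49 ± 0.62), Lncpint (−3.25 ± 0.73), Nr1d1 (−3.14 ± 0.77), Mical2 (−3.13 ± 0.83) and Fbxo32 (−3.08 ± 0.66) fell. In 9 of the 10 genes of largest change each OVA array lay on the called side of the PBS mean, and in Mical2 3 of 4 did.

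The calls in KitWsh_MC mice numbered 762, 453 higher and 309 lower, and 2383 (1246 and 1137) without KitWsh_MCigeR PBS array 2. The share of higher genes was 59.4%, 50.6% after quantile normalisation, 50.7% after centring and 48.8% (463 and 485 genes) with the mean of a gene's probe sets, so the excess of higher genes did not hold throughout. Another split of the same 7 arrays called 798 genes, so chance could not be excluded for the count. Leaving out any 1 of the compared arrays other than KitWsh_MC OVA arrays 3 and 4 moved the count by over 1.5 times, the lowest being 255 (KitWsh_MC PBS array 3). Slc26a4, Chil4, Saa3, Arg1, Fabp1 and Fbxo32 kept their call under every such omission. Of 17 cell cycle genes 12 rose and none fell, 15 rising when adjusted over the list alone (Rrm2 3.13 ± 0.54, Ccna2 2.75 ± 0.48, Birc5 2.66 ± 0.46; adjusted p = 6.17e-15, and adjusted p = 0.0847 with an estimated correlation). Of 13 inflammatory genes 9 rose, 10 when adjusted over the list alone (Saa3, Il6 3.43 ± 0.57, at least 1.73-fold, Cxcl1 2.96 ± 0.58, at least 6.11-fold, Ccl9 2.65 ± 0.45; adjusted p = 8.56e-11, and adjusted p = 0.0847 with an estimated correlation). Of 17 monocyte and macrophage genes 8 rose, 11 when adjusted over the list alone (Gpnmb 3.41 ± 0.88, Trem2 2.55 ± 0.70, at least 2.41-fold, Ms4a7 2.41 ± 0.58; adjusted p = 1.32e-07, and adjusted p = 0.225 with an estimated correlation). The IL-4 and IL-13 response list had 6 risers, and 10 risers with 1 faller when adjusted over the list alone (adjusted p = 3.75e-08, and adjusted p = 0.118 with an estimated correlation), the goblet cell list 5, and 9 when adjusted over the list alone (adjusted p = 4.05e-08, and adjusted p = 0.171 with an estimated correlation), and the matrix and remodelling list 6 of 20, and 7 when adjusted over the list alone (Timp1 5.65 ± 0.74, Tnc 2.73 ± 0.50; adjusted p = 0.000929, and adjusted p = 0.729 with an estimated correlation). The mast cell list had 3 risers of 7, and 5 when adjusted over the list alone (adjusted p = 2.71e-04, and adjusted p = 0.0847 with an estimated correlation).

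In KitWsh_MCifngR mice, the mast cell genes Cpa3 and Rab27b rose and clock genes moved both ways, while goblet and type 2 transcripts varied between the 4 OVA arrays. Cpa3 rose by 3.13 ± 0.56 (adjusted p = 0.0125), at least 5.28-fold, from 4.28 ± 0.95 (SD, n = 3) to 7.40 ± 1.70 (n = 4), and Rab27b by 1.01 ± 0.20. Cma1 (2.49 ± 0.64, adjusted p = 0.122) and Tpsb2 (2.19 ± 0.53, adjusted p = 0.106) did not pass. The clock transcripts Npas2 (2.88 ± 0.35, at least 1.92-fold, adjusted p = 5.51e-05) and Arntl (2.82 ± 0.59, at least 5.70-fold) rose, and Dbp (−3.38 ± 0.64), Per3 (−2.25 ± 0.44), Hlf (−2.15 ± 0.45) and Tef (−1.57 ± 0.30) fell. Sirpb1a (1.81 ± 0.35) and Kcne3 (1.66 ± 0.36, at least 2.16-fold) rose and Tspan4 (−1.98 ± 0.38) fell. Clca1 reached 4.73 in KitWsh_MCifngR OVA array 1, within the PBS range, with a group mean of 11.70 ± 4.65, and was not called. The beta-actin difference of that array was 4.81, and the same difference for the GAPDH control was 7.52. The GAPDH difference was 5.69 in OVA array 4, and 3.58 to 4.22 in the PBS arrays of this kind. It was 1.28 and 2.25 in OVA arrays 2 and 3, those of high Y-linked values. Whether RNA quality or the identity of the samples lies behind the variation was not tested. For all 10 genes of largest change each OVA array lay on the called side of the PBS mean.

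Only 18 genes were called in KitWsh_MCifngR mice, 12 higher and 6 lower, and 90 (50 and 40) without KitWsh_MCigeR PBS array 2. Lower genes were in the majority without the filter on low values (13 higher and 16 lower) and with the 4 doubted arrays left out (76 and 117), so neither direction held throughout. Leaving out any 1 of the 7 compared arrays moved the count by over 1.5 times, to between 1 (KitWsh_MCifngR PBS array 3) and 79 (KitWsh_MCifngR OVA array 1), and Npas2 alone of the 10 genes kept its call under every omission. The mast cell list shifted up (adjusted p = 2.03e-12), and this call held with an estimated correlation (adjusted p = 3.31e-04), with 2 of 7 members rising and 5 when adjusted over the list alone. Clock genes had 2 risers and 3 fallers of 12, and 3 risers and 7 fallers when adjusted over the list alone. No goblet cell gene was called by limma, and 3 of 10 rose when adjusted over the list alone (adjusted p = 2.47e-05, and adjusted p = 0.295 with an estimated correlation). The B cell list shifted down (mean −0.76; adjusted p = 3.32e-05, and adjusted p = 0.336 with an estimated correlation) with none of 12 called by limma, adjusted over the list alone or not, and its mean was 0.26 without the 4 doubted arrays, the array of low Kit and those of high Y-linked values among them. With all arrays 630 genes had an unadjusted p under 0.05.

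In KitWsh_MCigeR mice most of the called differences shrank when KitWsh_MCigeR PBS array 2 was left out, their median in the called direction going from 1.28 to 0.29. Clca1 was higher after challenge by 6.37 ± 1.76 (adjusted p = 0.0458) with all arrays and by 6.91 without that array (adjusted p = 0.618), and Chil4 by 5.63 ± 1.27 (at least 12.6-fold) and 5.74 (adjusted p = 0.324). Adipoq was lower, by −2.92 ± 0.73 (at least 1.74-fold) and −2.82. By contrast H2-K1 went from 3.78 ± 1.30 to 0.06, Ctsz from 3.74 ± 1.25 to 0.29 and Chia1 from 3.63 ± 0.90 to 1.27. Among the lower genes Rpl27a went from −2.85 ± 0.86 to −2.26, Sfi1 from −2.62 ± 0.58 (at least 1.88-fold) to −1.55, Fabp1 from −2.39 ± 0.62 to −1.87 and Phyhipl from −2.34 ± 0.70 (at least 1.73-fold) to −1.34. With all arrays 2199 genes were called, 1852 higher and 347 lower, with 84.2% higher, 53.7% after quantile normalisation, 45.4% after centring, and a median of all genes of 0.38. Without the array limma called 0 genes, and 737 had an unadjusted p under 0.05. Each other omission moved the count by over 1.5 times too, to 0 without KitWsh_MCigeR OVA array 1, 2 or 4 (unadjusted p under 0.05 in 4427, 4695 and 4469 genes), 561 without array 3, and 6212 and 6260 without KitWsh_MCigeR PBS arrays 1 and 3. Endothelial genes (7 of 14 higher) and alveolar type 2 genes (6 of 10 higher) led the list calls, with 10 and 8 higher when adjusted over the list alone (adjusted p = 0.027 each, and adjusted p = 0.938 with an estimated correlation), and none of these genes was called without the array. The goblet cell list shifted up only without it (adjusted p = 1.98e-04, and adjusted p = 0.699 with an estimated correlation). Of the 7 mast cell genes Hdc alone was higher (0.69 ± 0.24, adjusted p = 0.048), and by 0.37 without the array (adjusted p = 0.878).

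Transcripts of heart muscle and fat, tissues that lie beside the lung, averaged lower after challenge in several kinds of mice. The cardiac muscle list averaged 8.77 ± 0.66 in KitWsh PBS (SD, n = 3) and 7.58 ± 0.54 in KitWsh OVA (n = 4), 8.51 ± 0.49 and 7.54 ± 0.59 in KitWsh_MC, and 9.66 ± 0.41 and 8.50 ± 0.60 in KitWsh_MCifngR mice, with the same numbers of arrays. It shifted down in KitWsh (adjusted p = 2.56e-04, and adjusted p = 0.401 with an estimated correlation), KitWsh_MC (adjusted p = 0.00339, and adjusted p = 0.805 with an estimated correlation) and KitWsh_MCifngR mice (adjusted p = 7.07e-08, and adjusted p = 0.258 with an estimated correlation), with none of its 11 genes called by limma, adjusted over the list alone or not. In WT mice it averaged 8.45 ± 1.17 in PBS and 8.32 ± 0.32 in OVA (n = 4 each). In KitWsh_MCigeR mice it averaged 8.01 ± 1.19 in PBS (n = 3) and 8.01 ± 0.96 in OVA (n = 4). The adipose list, of 2 genes, averaged 7.84 ± 0.40 in WT PBS and 6.72 ± 0.80 in WT OVA, 7.56 ± 0.99 and 6.68 ± 0.26 in KitWsh and 7.51 ± 0.27 and 6.32 ± 0.43 in KitWsh_MCifngR mice. It did not pass as a list (adjusted p = 0.482, 0.463 and 0.0676), and Adipoq in WT mice was the only call among these, with 1 of 2 genes lower in each kind when adjusted over the list alone. The amount of tissue taken along with the lung was not measured.

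Clock transcripts differed between groups in opposite directions. Arntl averaged 7.43 ± 0.32 in WT PBS (SD, n = 4), 4.84 ± 1.15 in WT OVA (n = 4), 4.82 ± 0.11 in KitWsh PBS (n = 3), 4.36 ± 0.60 in KitWsh OVA (n = 4), 4.55 ± 0.57 in KitWsh_MC PBS (n = 3), 5.09 ± 0.84 in KitWsh_MC OVA (n = 4), 4.69 ± 0.35 in KitWsh_MCifngR PBS (n = 3), 7.51 ± 0.79 in KitWsh_MCifngR OVA (n = 4), 6.80 ± 1.78 in KitWsh_MCigeR PBS (n = 3) and 7.87 ± 0.22 in KitWsh_MCigeR OVA (n = 4). Dbp, which peaks at the opposite phase of the day, averaged 9.37 ± 0.50, 10.69 ± 1.58, 10.94 ± 0.62, 11.87 ± 0.15, 11.52 ± 0.37, 9.66 ± 0.36, 11.01 ± 0.41, 7.63 ± 1.35, 7.57 ± 1.43 and 5.89 ± 0.32 in the same groups. In KitWsh_MCigeR PBS arrays 1, 2 and 3 Arntl was 7.57, 4.77 and 8.07 and Dbp 7.32, 9.12 and 6.29, so outside the low-correlation array Arntl was high without challenge too. The labels give no time of collection.

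**Figure D4:**
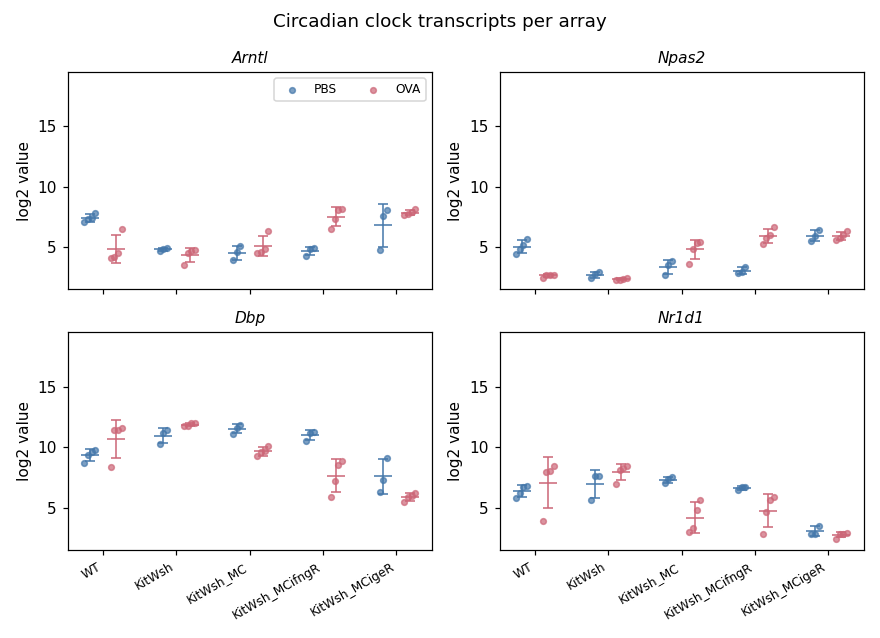
Log2 values of the clock transcripts Arntl, Npas2, Dbp and Nr1d1 in each array (points) by kind of mouse, PBS in blue and OVA in red, with group means and SD (bars). Arntl averages 7.87 and Dbp 5.89 in KitWsh_MCigeR OVA, against 4.36 and 11.87 in KitWsh OVA.

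Across the 11600 genes, the OVA response of WT mice was most like that of KitWsh_MC mice (r = 0.658), then of KitWsh (0.506), KitWsh_MCigeR (0.389) and KitWsh_MCifngR mice (0.122). The WT and KitWsh_MC responses shared 32 higher and 30 lower called genes, where independent lists would share 2.42 and 2.56. KitWsh_MC responses correlated at 0.426 with KitWsh, 0.338 with KitWsh_MCifngR and 0.127 with KitWsh_MCigeR, and KitWsh_MCigeR at 0.160 with KitWsh and 0.157 with KitWsh_MCifngR. Without KitWsh_MCigeR PBS array 2 the KitWsh_MCigeR response correlated at 0.670 with WT, above the 0.658 of KitWsh_MC, and at 0.345 with KitWsh, 0.470 with KitWsh_MC and 0.161 with KitWsh_MCifngR. Over genes called in either comparison on all arrays the WT and KitWsh_MC responses correlated at 0.800.

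Whether the response differed between kinds of mice was tested directly. KitWsh and WT mice differ in the sash mutation, so their comparison is not one of mast cells alone. The mast cell list averaged 5.59 ± 0.12 in WT OVA and 5.72 ± 0.27 in KitWsh OVA lungs. Between KitWsh and WT mice, Treml4 alone differed, its response being higher in KitWsh by 2.37 ± 0.40 (n = 4 KitWsh OVA, 3 KitWsh PBS and 4 in each WT group). Without KitWsh_MCigeR PBS array 2 there were 21 genes. Treml4 lost its call, and limma called 0 genes, without any 1 of WT OVA array 2, WT PBS arrays 2 and 3, KitWsh OVA arrays 2, 3 and 4 and KitWsh PBS arrays 2 and 3 (unadjusted p under 0.05 in 548 to 764 genes), while 6 genes were called without WT OVA array 4 and 2 without KitWsh PBS array 1. On all arrays 782 genes had an unadjusted p under 0.05, and the simulated recovery for this test was 15% of genes changed 2-fold and 72% of those changed 4-fold. With the spread taken without KitWsh_MCigeR PBS array 2 the recovery was 36% and 88%. Cell cycle genes shifted up in KitWsh relative to WT with none of 17 called by limma and 1 adjusted over the list alone (adjusted p = 4.25e-09, and adjusted p = 0.486 with an estimated correlation).

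Engraftment of MC cells went with a larger response of Saa3, Arg1, Timp1, Fxyd4 and Ccl12. Between KitWsh_MC and KitWsh mice (n = 4 OVA and 3 PBS arrays each), the response was larger by 6.86 ± 1.38 for Saa3, 5.41 ± 1.22 for Arg1, 5.10 ± 1.04 for Timp1, 4.00 ± 0.91 for Fxyd4 and 3.61 ± 0.80 for the monocyte chemokine gene Ccl12. Timp1 went from 5.26 ± 0.31 to 10.91 ± 0.37 in KitWsh_MC mice and from 4.88 to 5.44 in KitWsh mice. The response was lower by −4.19 ± 0.88 for Fabp1, −3.83 ± 0.92 for Rb1cc1, −3.23 ± 0.76 for Neurl3, −2.68 ± 0.47 for Siglecf (adjusted p = 0.0117) and −2.64 ± 0.60 for Bex2. The mast cell list had no called member by limma, 5 of 7 higher when adjusted over the list alone (adjusted p = 6.44e-04, and adjusted p = 0.241 with an estimated correlation), and the inflammatory list 1 of 13, and 4 when adjusted over the list alone (adjusted p = 4.11e-04, and adjusted p = 0.87 with an estimated correlation). The matrix and remodelling list had 1 of 20 higher, and 5 when adjusted over the list alone, and did not shift (adjusted p = 0.0726), nor did the monocyte and macrophage list (none of 17 called by limma, 1 adjusted over the list alone; adjusted p = 0.367). In all 60 genes were called, 46 higher and 14 lower (76.7% higher, 56.5% after quantile normalisation, 63.6% after centring), and 641 (484 and 157) without KitWsh_MCigeR PBS array 2. Leaving out any array other than KitWsh_MC OVA arrays 1 and 4 and KitWsh OVA array 1 moved the count by over 1.5 times, to between 2 (KitWsh PBS array 2) and 214 (KitWsh_MC OVA array 3), and none of the 10 named genes kept its call under every omission. An unadjusted p under 0.05 was reached by 1351 genes.

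The KitWsh_MCifngR and KitWsh_MCigeR responses were set against that of KitWsh_MC mice, which bears on mast cell receptors only if the labels are those of the engrafted cells. Between KitWsh_MCifngR and KitWsh_MC mice the response of Aldh1a3, which makes retinoic acid, was smaller by −3.52 ± 0.47 (adjusted p = 0.000323) and that of the metallothionein gene Mt2 by −2.28 ± 0.42, while it was larger by 2.60 ± 0.47 for Siglecf and 2.02 ± 0.38 for Heph. Aldh1a3 averaged 2.24 ± 0.01 in KitWsh_MCifngR OVA (SD, n = 4), 2.26 ± 0.03 in KitWsh_MCifngR PBS (n = 3), 5.72 ± 1.18 in KitWsh_MC OVA (n = 4) and 2.23 in KitWsh_MC PBS (n = 3). These 4 were the only calls, with 172 without KitWsh_MCigeR PBS array 2. Omissions of other arrays gave 1 to 101 genes (101 without KitWsh_MCifngR OVA array 4), all over 1.5 times from 4 except those of KitWsh_MC OVA arrays 1 and 2 and KitWsh_MCifngR PBS array 1, and Aldh1a3 alone kept its call under each. Cell cycle genes shifted down with none of 17 called by limma and 11 lower when adjusted over the list alone (adjusted p = 6.28e-11, and adjusted p = 0.685 with an estimated correlation). An unadjusted p under 0.05 was reached by 1167 genes.

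Between KitWsh_MCigeR and KitWsh_MC mice, the response was smaller for Il6 (−4.33 ± 0.81), Fxyd4 (−4.07 ± 0.91), Cdca8 (−3.67 ± 0.67), Rrm2 (−3.66 ± 0.77) and Ffar2 (−3.66 ± 0.84) and larger for Mcc (2.92 ± 0.62), Lipg (2.86 ± 0.62), Klf15 (2.66 ± 0.53), Nav2 (2.25 ± 0.42) and Lrguk (2.13 ± 0.49). All 10 lost their call without KitWsh_MCigeR PBS array 2, and also without any 1 of KitWsh_MC PBS arrays 1, 2 and 3, KitWsh_MC OVA array 2 and KitWsh_MCigeR OVA array 2. The differences did not go away with the calls. Without KitWsh_MCigeR PBS array 2 they were −3.38 for Il6, −4.38 for Fxyd4, −3.16 for Cdca8, −2.83 for Rrm2, −2.65 for Ffar2, 1.96 for Mcc, 2.08 for Lipg, 2.07 for Klf15, 1.80 for Nav2 and 1.70 for Lrguk (adjusted p from 0.0582 to 0.112), and no omission left under 67.1% of a size. With all arrays 34 genes were called, 11 higher and 23 lower (25 and 16 with the mean of a gene's probe sets), with a median of all genes of 0.37, and 3 were called without that array. Omissions of the other compared arrays gave 1 to 4607 genes (4607 without KitWsh_MCigeR PBS array 3), each over 1.5 times from 34. Of 17 cell cycle genes 3 were lower, and 9 when adjusted over the list alone (adjusted p = 2.00e-10, and adjusted p = 0.646 with an estimated correlation).

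Among OVA-challenged mice, where the low-correlation array entered only through the shared spread, KitWsh_MC lungs differed widely from KitWsh lungs. Arg1 was higher by 6.33 ± 0.80 (adjusted p = 3.41e-05), averaging 9.97 ± 1.61 against 3.64 ± 0.59 (SD, n = 4 each), at least 31.3-fold. Timp1 (5.47 ± 0.68), Saa3 (5.46 ± 0.91), the acute-phase gene Orm1 (4.16 ± 0.83, at least 3.66-fold) and Fxyd4 (4.15 ± 0.59, at least 7.67-fold) were higher too. Of the mast cell list Cma1 (3.94 ± 0.59, at least 5.58-fold), Cpa3 (3.13 ± 0.52, at least 2.46-fold), Tpsb2 (2.47 ± 0.50) and Hdc (1.24 ± 0.22) were higher. Nr1d1 (−3.75 ± 0.71), the basophil protease gene Mcpt8 (−2.82 ± 0.52, at least 1.41-fold), the neutrophil granule gene Ngp (−2.56 ± 0.80), Mr1 (−2.52 ± 0.63) and Nox4 (−2.46 ± 0.51) were lower. Each of the 4 KitWsh_MC arrays lay on the called side of the KitWsh mean for all 10 genes of largest change.

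The total between these OVA groups was 1027, 633 higher and 394 lower, and 3655 (1729 and 1926) without KitWsh_MCigeR PBS array 2, so the excess of higher genes did not remain. With the beta-actin covariate and that array left out there were 1765, with 778 of the 1027 among them. The share of higher genes was 61.6%, 49.4% after quantile normalisation and 42.5% after centring. The count fell to 401 without KitWsh_MC OVA array 2, 609 without KitWsh OVA array 2 and 341 without KitWsh OVA array 3. Of the 10 genes of largest change 8 kept their call under every omission, not Ngp and Mr1. The mast cell list had 4 higher of 7, also 4 when adjusted over the list alone (adjusted p = 6.91e-05, and adjusted p = 0.0656 with an estimated correlation). Of 13 inflammatory genes 7 were higher, also 7 when adjusted over the list alone (Il6 3.20 ± 0.53, at least 1.73-fold, Cxcl1 2.27 ± 0.54; adjusted p = 6.91e-05, and adjusted p = 0.882 with an estimated correlation). Of 11 Th1, NK and cytotoxic cell genes 3 were lower, and 5 when adjusted over the list alone (Ccl5 −1.66 ± 0.53, Klrk1 −1.38 ± 0.37, at least 1.28-fold, Cxcr3 −1.36 ± 0.38; adjusted p = 0.0259, and adjusted p = 0.882 with an estimated correlation). Npas2 was higher (2.47 ± 0.33) and 4 of the other clock genes lower, Nr1d1, Dbp (−2.21 ± 0.59) and Ciart (−1.38 ± 0.36) among them, with 1 higher and 6 lower adjusted over the list alone.

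OVA-challenged KitWsh_MCifngR lungs had less Arg1, Fxyd4, Timp1, Aldh1a3 and Orm1 than KitWsh_MC lungs. Arg1 was lower by −4.76 ± 0.80, Fxyd4 by −3.69 ± 0.59, Timp1 by −3.61 ± 0.68, Aldh1a3 by −3.49 ± 0.31 (at least 1.65-fold, adjusted p = 3.78e-08) and Orm1 by −3.14 ± 0.83, with Arg1 averaging 5.21 ± 1.64 against 9.97 ± 1.61 (SD, n = 4 each). Pon1 (2.80 ± 0.46), Upk1b (2.48 ± 0.44), Kif9 (2.44 ± 0.52) and Gfra1 (2.43 ± 0.32) were higher. The Y-linked Eif2s3y (3.66 ± 1.25, at least 1.82-fold) was higher in 2 of 4 arrays, those of high Y-linked values, and in the others at its KitWsh_MC level. Orm1 was lower in 3 of 4 arrays, and the other 8 genes differed in the called direction in each array. Cpa3 and Cma1 did not differ (1.10 ± 0.52, adjusted p = 0.160, and 0.31 ± 0.59, adjusted p = 0.778), and Rab27b was higher by 1.16 ± 0.19, the only call of the 7 mast cell genes.

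This comparison called 1527 genes, 1206 higher and 321 lower, and 4257 (3390 and 867) without KitWsh_MCigeR PBS array 2, all of them still called with the beta-actin covariate (4927 in total). The beta-actin difference averaged 3.38 in KitWsh_MCifngR OVA and 3.34 in KitWsh_MC OVA, so the covariate could hardly move this comparison and says little on RNA quality. The GAPDH difference, 4.19 ± 2.92 against 3.55 ± 2.16, was not used as a covariate. The share of higher genes was 79.0%, 59.1% after quantile normalisation and 61.4% after centring, with a median of all genes of 0.18. The count fell to 973 without KitWsh_MC OVA array 2, 914 without KitWsh_MC OVA array 3, 830 without KitWsh_MCifngR OVA array 1 and 1002 without KitWsh_MCifngR OVA array 3. Of the 10 genes of largest change 8 kept their call under every omission, not Eif2s3y and Orm1. Of 14 IL-4 and IL-13 response genes 3 were lower, also 3 when adjusted over the list alone (adjusted p = 2.12e-06, and adjusted p = 0.474 with an estimated correlation). Of 13 inflammatory genes 6 were lower, also 6 when adjusted over the list alone (Il6 −2.88 ± 0.53, at least 1.73-fold; adjusted p = 3.03e-05, and adjusted p = 0.63 with an estimated correlation). Plasma cell genes had 3 lower of 12, also 3 when adjusted over the list alone (adjusted p = 4.09e-05, and adjusted p = 0.474 with an estimated correlation). Structural and muscle lists averaged higher in KitWsh_MCifngR OVA lungs without passing as lists, namely the ciliated cell list (0.55, 2 of 13 higher, also 2 over the list alone, adjusted p = 0.132), mesothelium (0.60, 1 of 5, also 1 over the list alone, adjusted p = 0.596), endothelium (0.45, adjusted p = 0.528) and cardiac muscle (0.96, adjusted p = 0.121), the last 2 with none called by limma. The single measured skeletal muscle gene averaged 5.75 ± 2.30 against 3.98 ± 0.62 and was not called. A difference in the make-up of the tissue is not excluded here.

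OVA-challenged KitWsh_MCigeR lungs, compared with KitWsh_MC, had lower Arg1 (−5.11 ± 0.80, adjusted p = 0.000895; 4.86 ± 1.79 against 9.97 ± 1.61, SD, n = 4 each), Ccl11 (−4.05 ± 0.75, at least 4.63-fold), Timp1 (−3.88 ± 0.68), Agr2 (−3.81 ± 0.80) and the clock gene Dbp (−3.78 ± 0.59). Cyp1a1 (4.03 ± 0.74, at least 10.2-fold), Zbtb16 (3.29 ± 0.64), Spon2 (2.80 ± 0.63, at least 3.14-fold), the clock gene Arntl (2.78 ± 0.54) and Map3k6 (2.31 ± 0.41) were higher. Each of the 4 KitWsh_MCigeR arrays lay on the called side of the KitWsh_MC mean for all 10. Cma1 was lower by −2.46 ± 0.59 (adjusted p = 0.0208), while Cpa3 (−1.81 ± 0.52, adjusted p = 0.0521) and Tpsb2 (−1.64 ± 0.50, adjusted p = 0.0622) did not pass.

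In this pair 340 genes were called, 150 higher and 190 lower, and 2434 (1553 and 881) without KitWsh_MCigeR PBS array 2, where higher genes were in the majority. The share of higher genes was 44.1%, 52.0% after quantile normalisation and 53.2% after centring. The beta-actin difference averaged 1.95 in KitWsh_MCigeR OVA and 3.34 in KitWsh_MC OVA. With it as a covariate and that array left out, 797 genes were called, 265 of the 340 (77.9%) and 731 of the 2434 (30%) among them. The 75 of the 340 no longer called had a median of 1.00 before and 0.73 after in the called direction, with a median standard error of 0.25 both times, and all 10 named genes kept their call. The count was 90 without KitWsh_MC OVA array 2, 600 without KitWsh_MC OVA array 4, and 131, 121 and 96 without KitWsh_MCigeR OVA arrays 2, 3 and 4. Of the 10 named genes 8 kept their call under every omission, not Spon2 and Agr2. Of 13 inflammatory genes 4 were lower, and 6 when adjusted over the list alone (adjusted p = 1.21e-05, and adjusted p = 0.648 with an estimated correlation). Of 17 cell cycle genes 4 were lower, and 5 when adjusted over the list alone (Rrm2 −2.15 ± 0.50, Ccna2 −1.85 ± 0.44, Birc5 −1.81 ± 0.43, Mcm5 −1.76 ± 0.42; adjusted p = 4.07e-06, and adjusted p = 0.648 with an estimated correlation). The mast cell list had 1 lower of 7, and 5 lower and 2 higher when adjusted over the list alone (adjusted p = 0.0442, and adjusted p = 0.648 with an estimated correlation).

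Without challenge, KitWsh lungs had more of the neutrophil granule transcripts Ngp and Camp than WT lungs, and less Kit. Ngp (4.32 ± 0.86) and Camp (3.77 ± 0.55, at least 4.99-fold) were higher in KitWsh PBS mice (n = 3) than in WT PBS mice (n = 4), Camp averaging 7.32 ± 0.73 against 3.55 ± 0.85 (SD). Hpcal4 (2.28 ± 0.48), Clec12b (2.04 ± 0.33) and Ppp4r3a (1.96 ± 0.44) were higher as well. Besides Kit, Endod1 (−3.06 ± 0.66), Spon2 (−2.89 ± 0.68, at least 3.76-fold), Inpp4b (−2.73 ± 0.56, at least 1.17-fold) and Arntl (−2.61 ± 0.59, at least 5.39-fold) were lower, as was Siglecf, a marker of alveolar macrophages and eosinophils (−1.83 ± 0.33). Among the genes between Corin and Kit, a region near the sash mutation, 1 of 17 was lower (Kit itself) and none higher. Each of the 3 KitWsh arrays lay on the called side of the WT mean for all 10 genes of largest change.

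The count was 137, 87 higher and 50 lower (63.5% higher, 49.0% after quantile normalisation, 52.1% after centring), and 919 (653 and 266) without KitWsh_MCigeR PBS array 2. Leaving out any 1 of the 7 compared arrays moved it by over 1.5 times, to between 20 (KitWsh PBS array 2) and 246 (WT PBS array 4), and Kit, Camp and Clec12b kept their call under every omission. Neutrophil genes had 2 higher of 10, also 2 when adjusted over the list alone, and the list did not pass as a whole (adjusted p = 0.159). Alveolar macrophage genes had 1 lower of 9, and 2 when adjusted over the list alone (adjusted p = 8.44e-04, and adjusted p = 0.6 with an estimated correlation). Clock genes had 1 higher and 2 lower of 12, Tef (1.91 ± 0.30) and Npas2 (−2.33 ± 0.35, at least 1.04-fold) among them, and 7 higher and 2 lower when adjusted over the list alone.

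MC engraftment without challenge (n = 3 KitWsh_MC PBS and 3 KitWsh PBS arrays) left the mast cell list without a called gene, Cma1 differing by 1.57 ± 0.68 (adjusted p = 0.296). Lncpint (4.26 ± 0.78, at least 6.32-fold), Endod1 (4.10 ± 0.71), Spag17 (3.39 ± 0.72, at least 6.15-fold), Zbed6 (3.02 ± 0.70), Rb1cc1 (2.88 ± 0.70) and Siglecf (1.42 ± 0.35) were higher in KitWsh_MC mice. Klhl42 (−2.82 ± 0.48), the matrix gene Thbs1 (−2.66 ± 0.58), Chn1 (−2.33 ± 0.54), Ppp4r3a (−1.85 ± 0.48) and Tbc1d19 (−1.84 ± 0.46) were lower. For all 10 genes of largest change each KitWsh_MC array lay on the called side of the KitWsh mean. The count was 139, 78 higher and 61 lower, with a median of all genes of −0.14, and 1389 (388 and 1001) without KitWsh_MCigeR PBS array 2, where lower genes were in the majority. Leaving out any 1 of the 6 compared arrays moved it by over 1.5 times, to between 12 (KitWsh_MC PBS array 2) and 70 (KitWsh_MC PBS array 1), and of the 10 genes Endod1 and Klhl42 kept their call under every omission. Of 9 alveolar macrophage genes 1 was higher, and 3 when adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.965 with an estimated correlation).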

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

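All tests of causes, the counts over other splits of the arrays, and the grouping of named genes by array in this part were chosen after the results were seen.

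The response to challenge was compared between kinds of mice. Tests of the difference between responses called 1 gene between KitWsh and WT mice (Treml4, 2.37), 60 between KitWsh_MC and KitWsh, 4 between KitWsh_MCifngR and KitWsh_MC and 34 between KitWsh_MCigeR and KitWsh_MC. With engrafted MC cells the response of Saa3 was larger by 6.86, Arg1 by 5.41, Timp1 by 5.10, Fxyd4 by 4.00 and Ccl12 by 3.61, and that of Fabp1 (−4.19), Rb1cc1 (−3.83), Neurl3 (−3.23), Siglecf (−2.68) and Bex2 (−2.64) smaller. Between KitWsh_MCifngR and KitWsh_MC the genes were Siglecf (2.60), Heph (2.02), Aldh1a3 (−3.52) and Mt2 (−2.28). Between KitWsh_MCigeR and KitWsh_MC they were Mcc (2.92), Lipg (2.86), Klf15 (2.66), Nav2 (2.25), Lrguk (2.13), Il6 (−4.33), Fxyd4 (−4.07), Cdca8 (−3.67), Rrm2 (−3.66) and Ffar2 (−3.66) with the largest sizes. Over 100 splits drawn for each, 3 called as many as the 60 genes of KitWsh_MC and KitWsh, the real split among them. With a highest other of 250, chance was not firmly excluded there. Chance could not be excluded for the 1 of KitWsh and WT (5 splits, highest other 13), the 4 of KitWsh_MCifngR and KitWsh_MC (9 splits, highest other 233) or the 34 of KitWsh_MCigeR and KitWsh_MC (7 splits, highest other 1520). The splits redrew the kinds of mice separately among OVA arrays and among PBS arrays. A split could thus hold real differences between kinds, and some called several times the real count. These splits therefore cannot decide whether any of these counts came by chance. None of the 10 genes named for KitWsh_MC and KitWsh kept its call whichever array was left out, though each kept at least 72.8% of its size.

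The 2199 genes between OVA and PBS KitWsh_MCigeR mice were set against the quality of KitWsh_MCigeR PBS array 2. Without it, limma called 0 genes (737 at an unadjusted p under 0.05), but it also called 0 without KitWsh_MCigeR OVA array 1, 2 or 4 (4427, 4695 and 4469 at that p), so the fall to 0 does not single out the array. Poor quality of that array may be the source, since the median in the called direction was 0.29 without it and 1.25 to 1.75 without any other compared array. A response of these mice to challenge as the source of the calls is excluded for most, since 17% of the 2199 kept at least 50% of their log2 fold change without the array, and 100% did without any other. Clca1, Chil4 and Adipoq were among those whose size hardly moved, and a response of such genes stays open. Chance could not be excluded for the count (2 splits as large, highest other 2472 against 2199).

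The WT OVA array 4 went against its labels, with Y-linked transcripts at 7.28, Kit at 6.90 and Xist at 10.69. RNA of 1 male mouse is excluded by the Xist value of 10.69. A swap with a KitWsh array is excluded, as the highest Kit among these was 7.52 and the lowest in another WT array 9.86. RNA of a male and a female mouse, both with little Kit, was not excluded. The female share by Xist (21.7%) and the male share by Y-linked transcripts (85.9%) came to 108%. Kit stood at 6.99% of the mean of the other WT OVA arrays and at 12.8% of the lowest other WT array. The male share averages transcripts that disagreed. Against KitWsh_MCifngR OVA arrays 2 and 3, Kdm5d was higher (7.08 against 6.52 and 6.48). Eif2s3y (9.07 against 9.81 and 9.25) and Uty (5.70 against 6.79 and 6.16) were lower. The sum therefore does not decide whether the RNA was mixed. A wrong label or RNA from outside the series stays open, and no biological explanation was tested. The mucus and macrophage genes Clca1 (10.69), Chil4 (6.89) and Arg1 (4.93) were also lowest in this array among WT OVA mice.

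Y-linked transcripts stood at 7.71 and 7.30 in KitWsh_MCifngR OVA arrays 2 and 3, with low Xist, against a female label. One of the 3 transcripts, Eif2s3y, was called between OVA KitWsh_MCifngR and OVA KitWsh_MC mice (3.66, adjusted p = 0.0493), and no cause was tested.

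Gene lists in which a single array lay far from the other 3 of its group, by the gap to its neighbour over the group's range, numbered 19 of 222 tests, and chance marks about 1 in 20 groups. In WT OVA they were the goblet cell (0.929, array 4 low) and targeted gene lists (0.960, array 4 low), and the Th1, NK and cytotoxic (0.874), type I interferon (0.887) and lymphoid chemokine lists (0.855), all with array 1 high. In KitWsh OVA they were the basophil (0.901) and alveolar macrophage lists (0.976), with array 3 low, the alveolar type 1 list (0.866, array 3 high), smooth muscle (0.834, array 2 low) and mesothelium (0.908, array 1 low). In KitWsh_MCifngR OVA the matrix (0.894) and alveolar type 2 lists (0.847) were low in array 1 and the targeted genes high in array 4 (0.966). Cell cycle was low in KitWsh_MC OVA array 2 (0.848), and club cell (0.912) and cardiac muscle (0.842) in KitWsh_MCigeR OVA array 2. In WT PBS neutrophil genes were high in array 4 (0.879), and T cell (0.908) and skeletal muscle genes (0.840) low in array 2.

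Among genes always named, Kit in WT OVA (0.912), Ifngr1 in KitWsh OVA (0.890) and WT PBS (0.911), Tpsb2 in KitWsh_MCifngR OVA (0.860, array 4 at 6.91) and WT PBS (0.989, at the floor), Hdc in KitWsh_MCigeR OVA (0.905) and KitWsh OVA (0.968) and Gata2 in WT PBS (0.968) had such an array. The other 89 named genes had 71 of 534 tests past it. They gathered in WT OVA array 4 (10 genes), KitWsh OVA array 1 (8), WT PBS array 4 (8), KitWsh OVA array 3 (7), KitWsh_MCigeR OVA array 3 (6) and KitWsh_MCifngR OVA array 4 (5).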

How the results depend on the processing

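Leaving out the array of lowest correlation with the others, leaving out 4 doubted arrays, and leaving out the first with a beta-actin covariate were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because the sample titles run from 1 to 36 and the groups share no numbers.

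Under alternatives other than single omissions, 2600 values of named genes kept their direction and their side of the threshold, 201 lost their call, 117 gained one and 1 reversed. For gene lists 1137 kept both, 204 lost their call and 3 reversed. With 1 array left out, 1916 gene values and 940 list values kept both, 510 and 109 lost their call, 21 gene values gained one and none reversed. The trend and robust options of eBayes moved no count by over 1.5 times.

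With KitWsh_MCigeR PBS array 2 left out, with the 4 doubted arrays left out, and with the first left out and the covariate, in that order, the counts of called genes were as follows. OVA against PBS gave 1081, 2192 and 1707 in WT, 760, 1113 and 1201 in KitWsh, 2383, 2656 and 2703 in KitWsh_MC, 90, 193 and 131 in KitWsh_MCifngR and 0 each time in KitWsh_MCigeR mice (limma, with 737, 821 and 1001 genes at an unadjusted p under 0.05). The difference of responses gave 21, 66 and 121 for KitWsh and WT, 641, 799 and 777 for KitWsh_MC and KitWsh, 172, 151 and 133 for KitWsh_MCifngR and KitWsh_MC, and 3, 35 and 72 for KitWsh_MCigeR and KitWsh_MC. Among OVA mice they were 3655, 3928 and 1765 for KitWsh_MC and KitWsh, 4257, 4028 and 4927 for KitWsh_MCifngR and KitWsh_MC, and 2434, 2677 and 797 for KitWsh_MCigeR and KitWsh_MC. Among PBS mice they were 919, 1101 and 1179 for KitWsh and WT, and 1389, 1526 and 1556 for KitWsh_MC and KitWsh. The omitted array widened the shared spread of every comparison, and the rise of the counts beyond that has a cause that was not tested.

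With array weights the counts were 5110 in WT, 4613 in KitWsh, 3643 in KitWsh_MC, 2031 in KitWsh_MCifngR and 101 in KitWsh_MCigeR mice, 2515, 2221, 2523 and 1306 for the 4 differences of responses, 3506, 4247 and 1700 for the 3 pairs of OVA groups, and 4854 and 3920 for the 2 pairs of PBS groups. The cause was not tested. With only the compared groups in the fit, which then rests on fewer arrays, they were 1340 in WT, 759 in KitWsh, 2 in KitWsh_MCifngR and 0 in KitWsh_MCigeR mice (limma, 330 genes at an unadjusted p under 0.05), 195 for the KitWsh and WT difference of responses, 191 for KitWsh_MC and KitWsh and 2 for KitWsh_MCigeR and KitWsh_MC, 550 and 451 for OVA KitWsh_MC against KitWsh and OVA KitWsh_MCifngR against KitWsh_MC, and 1864 and 2088 for the PBS pairs.

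Without a filter KitWsh_MCifngR mice gave 29 genes, KitWsh_MCigeR mice 6, and the KitWsh_MCifngR and KitWsh_MC difference of responses 12. The filter at log2 7, which leaves fewer genes, gave 503 in KitWsh_MC mice, 0 for the KitWsh and WT difference (limma, 594 genes at an unadjusted p under 0.05), 35 for KitWsh_MC and KitWsh, 2 for KitWsh_MCifngR and KitWsh_MC, 8 for KitWsh_MCigeR and KitWsh_MC, and 77 for PBS KitWsh_MC against KitWsh. Quantile normalisation gave 14 in KitWsh and 1174 in KitWsh_MCigeR mice, 2 for the KitWsh and WT difference, 9 for KitWsh_MCifngR and KitWsh_MC, 207 for KitWsh_MCigeR and KitWsh_MC, 1546 for OVA KitWsh_MC against KitWsh and 560 for OVA KitWsh_MCigeR against KitWsh_MC. Centring gave 13 in KitWsh mice, 2 for the KitWsh and WT difference, 11 for KitWsh_MC and KitWsh, 141 for KitWsh_MCigeR and KitWsh_MC, and 69 for PBS KitWsh_MC against KitWsh. The mean of probe sets gave 5 in KitWsh_MCigeR mice, 8 for the KitWsh_MCifngR and KitWsh_MC difference, 78 for PBS KitWsh against WT and 279 for PBS KitWsh_MC against KitWsh. The cause of these moves was not tested.

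With 1 of the compared arrays left out, the counts ranged from 14 to 593 in WT, 0 to 133 in KitWsh, 255 to 1052 in KitWsh_MC, 1 to 79 in KitWsh_MCifngR and 0 to 6260 in KitWsh_MCigeR mice (limma called 0 in KitWsh with 898 genes at an unadjusted p under 0.05). They ranged from 0 to 6 for the KitWsh and WT difference of responses, 2 to 214 for KitWsh_MC and KitWsh, 1 to 101 for KitWsh_MCifngR and KitWsh_MC, and 1 to 4607 for KitWsh_MCigeR and KitWsh_MC. Among OVA mice they ranged from 341 to 1303 for KitWsh_MC against KitWsh, 830 to 1845 for KitWsh_MCifngR against KitWsh_MC and 90 to 600 for KitWsh_MCigeR against KitWsh_MC, and among PBS mice from 20 to 246 for KitWsh against WT and 12 to 70 for KitWsh_MC against KitWsh.

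Over all comparisons 112 list shifts were called with the preset correlation and 1 with an estimated correlation, that of the mast cell list between OVA and PBS KitWsh_MCifngR mice. Only the correlation setting was changed between these runs, so the loss of the other 111 calls follows from it. The small adjusted p-values of those lists thus rest on the low preset value, and their shifts are not firm. The similarity of OVA responses between kinds of mice, a median r of 0.312 over the 10 pairs, was 0.513 over genes called in either comparison.

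The 4 reversals came with the 4 doubted arrays left out. The mean log2 fold change of the B cell list in KitWsh_MCifngR mice went from −0.76 to 0.26 between OVA and PBS, and from −0.67 to 0.35 between OVA KitWsh_MCifngR and KitWsh_MC mice. That of the lymphoid chemokine and follicle list in KitWsh_MCifngR mice went from −0.42 to 0.11 between OVA and PBS, and Eif2s3y, a Y-linked gene whose high arrays were among those omitted, to −0.01 between OVA KitWsh_MCifngR and KitWsh_MC mice. No reversed value was called. Only 2 KitWsh_MCifngR OVA arrays remained there, and the cause of the list reversals was not tested. Signal near the GCRMA floor limits fold changes of genes that were low in 1 group, such as Chil4, Arg1 and Aldh1a3.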

Other observations

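Immunoglobulin segment genes, passed over in the naming of genes, rose in part after challenge in KitWsh mice and were in part lower with MC cells. Of 15 tested, 2 rose between OVA and PBS KitWsh mice (median log2 fold change 1.13), none was called by limma in WT mice, where the median was 1.10, and 4 were lower in OVA KitWsh_MC than in OVA KitWsh mice (median −1.69). The 4 risers in KitWsh_MCigeR mice (median 1.83) were not called by limma without KitWsh_MCigeR PBS array 2, as no gene was.

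The tests of causes and the counts over other splits of the arrays in this part were chosen after the results were seen.

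Engrafted mast cells may explain part of the 1027 genes between OVA KitWsh_MC and OVA KitWsh mice, among them Arg1, Timp1 and Saa3. The fit with the beta-actin covariate also left out KitWsh_MCigeR PBS array 2, so it is set against the fit that left out this array alone, which called 3655 genes, all 1027 among them. With the covariate 75.8% of the 1027 (778) were still called the same way, and the median of the 1027 went from 0.99 to 0.78. Of the 3655 genes 41.8% (1529) were still called, their median going from 0.72 to 0.53. The beta-actin difference averaged 3.34 ± 1.93 in KitWsh_MC OVA and 1.74 ± 0.61 in KitWsh OVA, so the covariate goes with the groups. It therefore cannot exclude a difference in RNA quality as a cause. The 778, Arg1, Timp1 and Saa3 among them, kept a called difference beyond this 1 measure, and RNA quality stays open for all 1027. In the 249 no longer called the median went from 0.80 to 0.50 and the median standard error from 0.22 to 0.21, so the calls ended through the smaller difference. Between PBS mice of these kinds the median of the same genes was 0.21, with 70.9% in the same direction and 19 called. The genes were picked for their difference in OVA mice, so a smaller one in PBS mice was likely from the start. The test of the difference of responses called 60 genes, so a difference of these kinds of mice without challenge is not excluded. The time of day of tissue collection cannot be told apart from the groups, as 5 clock genes were called and the labels give no times. Chance could be excluded (1027 against a highest other of 57, and 3655 against 2420 with KitWsh_MCigeR PBS array 2 left out). Engraftment itself stays open, as untested by another design.

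For the other counts over all arrays, chance could be excluded for OVA against PBS in WT (158, highest other 12) and KitWsh mice (72, highest other 53), for OVA KitWsh_MCifngR against KitWsh_MC (1527, highest other 188), OVA KitWsh_MCigeR against KitWsh_MC (340, highest other 51) and PBS KitWsh against WT mice (137, highest other 108), the real split alone (1) giving as many. It could not be excluded for KitWsh_MC (762, highest other 798) or KitWsh_MCifngR mice (18, highest other 105), where 2 splits gave as many. Why a split called several times the real count in KitWsh_MCifngR mice was not tested. For PBS KitWsh_MC against KitWsh mice the 10 splits are too few (139, highest other 0 by limma). With KitWsh_MCigeR PBS array 2 left out, chance could no longer be excluded for KitWsh mice (760, highest other 881). The same held for PBS KitWsh against WT mice (919, highest other 940). In that fit the real split called the most in WT mice (1081, highest other 228). It did so too for OVA KitWsh_MCifngR against KitWsh_MC (4257, highest other 2230) and OVA KitWsh_MCigeR against KitWsh_MC (2434, highest other 1012). It did not in KitWsh_MC (2383, highest other 2512) or KitWsh_MCifngR mice (90, highest other 331). Splits that mixed the groups thus called many genes there too. For the 21 genes of the response of KitWsh minus WT mice 2 of 100 splits were as large (highest other 24). For the 641 of KitWsh_MC minus KitWsh 4 splits were as large (highest other 1972). Splits for a difference of responses could hold real differences between kinds, so chance was not excluded for either count.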
